A study of Mus musculus with 8 samples.

How the data were processed

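RNA of sorted leptotene and zygotene spermatocytes from Bend2 WT and KO mice of the C57BL/6 strain was sequenced, with 2 libraries in each of 4 groups, 8 in all. Per the labels' protocols, total RNA was extracted with TRIzol and the libraries were prepared together with a directional kit. Alignment with HISAT2 to mm10 (GRCm38) and the use of DESeq2 are named per the submitters' processing notes, which give no settings. Per the file headers, transcripts were assembled in each library on its own with StringTie 2.1.2, guided by Ensembl release 89, with no strand option given and with unannotated transcripts allowed. The deposited values are the mean read coverage per base, FPKM and TPM of each assembled transcript, and no read counts were used here. Without a strand option in the headers, overlapping and antisense genes are uncertain.

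The value of a gene was the sum of the deposited TPM of its transcripts. A transcript went to the reference gene that its file names, or else to the GENCODE M21 gene of the same strand that covers at least 50% of its exonic length. That assignment was chosen from the structure of the files and the likeness of replicates, before any test between groups. Of 27632 reference genes named in the files 27546 were in GENCODE M21, all on the same chromosome, and 33950 genes had a value. Genes held between 73.8% and 86.3% of the TPM of a library. The ratio of coverage to FPKM implied between 6.82 and 9.45 aligned gigabases per library. Read numbers are unknown, so no counting interval is given. Across genes, which are not independent replicates, the log2 values of the 2 libraries of a group correlated with r between 0.862 and 0.878, and between 20.8% and 25% of genes differed by over 2-fold between them.

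Values were scaled by median-of-ratios factors, and 23065 genes with a TPM of at least 1 in at least 2 libraries were tested on log2(scaled TPM + 1). A single limma 3.58.1 model in R 4.3.3 held the 4 group means over all 8 libraries, with eBayes and an intensity trend (4 residual degrees of freedom). The 5 comparisons were KO against WT at each stage, zygotene against leptotene in each genotype, and the interaction. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9. In simulated data, 0%, 26%, 48% and 80% of genes changed 2-, 4-, 8- and 16-fold in KO leptotene were recovered (21450 genes tested), and 0%, 32%, 70% and 78% in KO zygotene (21523 genes tested). Each simulation changed 200 genes, all with a mean log2(scaled TPM + 1) over 2, so low genes are not covered. Noise was drawn independently for each gene and library, so kinds of library and genes that move together are not covered either.

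The 28 gene lists cover spermatogonia, S phase, meiotic functions, later germ cells, chromatin repressors, BEN domain genes, stress, other testis cell types, Hox, ribosomal, mitochondrial and sex-linked genes. They were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, for lists with at least 5 tested members, adjusted over the lists of a comparison. Camera sets a list against all other tested genes, so its direction is relative to them and can differ from the sign of the median. The median log2 fold change of all genes in KO against WT was -0.065 at leptotene and -0.057 at zygotene. Members were also adjusted over the list alone. A list of histone cluster genes, taken by symbol with no check that each is replication-dependent, was added after values were seen. Named are the 10 largest rises and 10 largest falls among called genes of each KO comparison whose libraries do not overlap, without unnamed gene models, and up to 5 each way for the stage comparisons and the interaction. For each list up to 2 called members each way are named, or the most abundant member where none was called. Overlap of calls was tested with Fisher's exact test, and the exon ratio of Gm15262 with an exact permutation test.

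The tests, lists, naming rule and most alternatives were set before the data were examined. The alternatives were a pseudocount of 0.1 or 5, no filter or a TPM of at least 5, TPM as deposited, quantile normalization, FPKM, limma-voom on reads estimated from the coverage with an assumed length of 150, reference transcripts only, only the libraries of a comparison, the replicate number as a block, no intensity trend, a fold of at least 2, and leaving out each library. Chosen after seeing the data were the loci of the files, TPM recomputed from covered bases, a covariate for the kind of library (the share of TPM in unannotated single-exon transcripts) and the exon ratio of Gm15262. The design text speaks of 3 replications, and the labels used here give 2 libraries per group.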

Results

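RNA from leptotene and zygotene spermatocytes of 2-month C57BL/6 mice was sequenced to ask what loss of Bend2, which encodes a BEN domain protein, does to expression in early meiotic prophase. Leptotene is the stage at which meiotic chromosomes form their axes and receive programmed DNA breaks, and in zygotene homologous chromosomes begin to synapse. The cells had been sorted by flow cytometry from wild-type (WT) and Bend2 knockout (KO) testes. There were 4 groups of 2 libraries: WT leptotene, KO leptotene, WT zygotene and KO zygotene. Each library held between 6.82 and 9.45 aligned gigabases as its file implies, and 23065 genes were tested. Values are scaled TPM, given as mean ± SD over the 2 libraries of a group (n = 2). Fold changes are on the log2(scaled TPM + 1) scale, which understates the change of low genes, and carry their standard error. Nothing in the labels ties the libraries of a group to separate animals, so p-values measure the spread between these libraries, which can be technical. A gene listed at 0 had no transcript with a value assigned to it in the assembly of that library, which does not show that its RNA was absent.

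Bend2 was not analysed here under its own symbol, which none of the 33950 genes with a value carries. The X-linked protein-coding gene Gm15262 (chromosome X, 161287456 to 161366252, GRCm38) lies between Scml2 and Rai2, the neighbours of BEND2 on the human X chromosome. No table used here gives the identity of the 2 genes, and Gm15262 was singled out after its values were seen. Its scaled TPM was 39 and 15.1 in the WT leptotene libraries, 21.4 and 27 in KO leptotene, 28 and 16.5 in WT zygotene and 29.1 and 40.5 in KO zygotene. The whole-gene level did not pass the test at either stage (log2 fold change -0.02 ± 0.45, adjusted p = 1.0 at leptotene and 0.65 ± 0.45, adjusted p = 0.551 at zygotene). Exons 12 (161354991 to 161355112) and 13 (161357875 to 161358064) of its 15-exon transcript did separate the genotypes, and were chosen after the coverage was seen. Their coverage over that of exons 11 and 14 was 0.946 ± 0.408 in WT (SD, n = 4) and 0.105 ± 0.0807 in KO (SD, n = 4), with the lowest WT library at 0.455 and the highest KO library at 0.182. A two-sided exact permutation test of the 4 KO against the 4 WT libraries gave p = 0.0286, the smallest that its 70 arrangements allow. The test takes the 4 libraries of a genotype, from 2 stages, as independent, which was not shown.

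**Figure D1:**
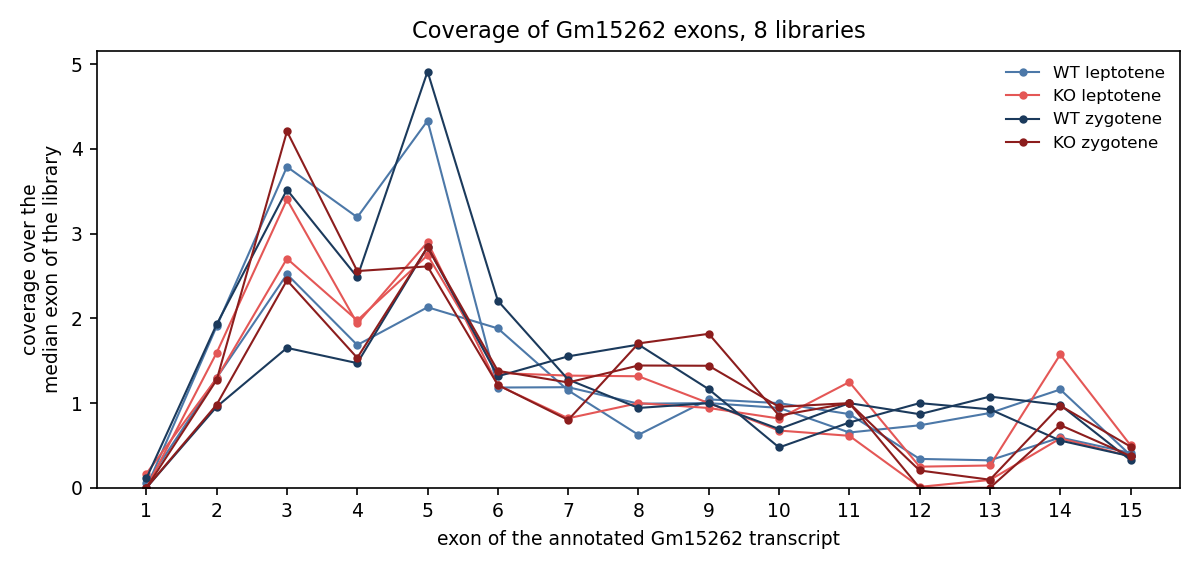
Coverage of the 15 annotated exons of Gm15262 (x axis, exon number) in each of the 8 libraries, as a ratio to the median exon of that library (y axis, no unit); each line is 1 library, coloured by group. Over exons 11 and 14, the coverage of exons 12 and 13 reaches at most 0.182 in KO and at least 0.455 in WT.

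The comparison of KO with WT leptotene cells asks what is altered when meiotic prophase begins without Bend2. Lists of later spermatogenesis were lower in KO at the preset correlation of camera and did not pass with an estimated one. 299 of 23065 genes changed, 25 higher and 274 lower (limma, adjusted p under 0.05), and all of them by at least 2-fold. Of these, 40 were listed at 0 in both libraries of WT or of KO. Tnp1, a transition protein that replaces histones in spermatids, fell from 809 ± 289 to 38.2 ± 12.3 (chromosome 1, 73015074 to 73015909, log2 fold change -4.36 ± 0.46, adjusted p = 0.0186). Akap4, a scaffold of the sperm fibrous sheath, fell from 213 ± 77.4 to 13.4 ± 5.76 (log2 fold change -3.91 ± 0.50). Cdkn2a, which encodes the cell cycle inhibitors p16INK4a and ARF, rose from 11.3 ± 0.969 to 50.3 ± 11.9 (chromosome 4, 89274471 to 89294653, log2 fold change 2.04 ± 0.27, adjusted p = 0.0208).

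Of the 30 round spermatid genes, 4 fell and none rose, 21 fell when adjusted over the list alone, and all 30 had a negative estimate. The round spermatid list had a median log2 fold change of -1.98 (camera adjusted p = 3.70e-16, and adjusted p = 0.54 with an estimated correlation). Of the 30 pachytene spermatocyte genes, 8 fell, or 19 adjusted over the list alone. The pachytene spermatocyte list had a median log2 fold change of -1.34 (camera adjusted p = 4.81e-11, and adjusted p = 0.54 with an estimated correlation). Pgk2, the glycolytic enzyme of later germ cells, fell from 107 ± 29.2 to 9.88 ± 4.48, and Meig1, needed for spermatid differentiation, from 117 ± 24 to 11.6 ± 4.56. Among the largest falls outside the lists, Hmgb4 went from 73 ± 25.3 to 2.80 ± 0.191, and Txndc2, a sperm thioredoxin, from 80.8 ± 19.5 to 3.83 ± 0.44. Tcte3 measured 151 and 113 in the WT libraries and 0 and 8.66 in the KO libraries (adjusted p = 0.0318). Hmgb1-rs17, an annotated pseudogene, fell from 25.5 ± 5.30 to 0.0959 ± 0.0254, and near-identical copies make its value uncertain. Of 27 piRNA pathway genes only Tdrd6, a protein of the chromatoid body, was called, falling from 42.7 ± 0.513 to 8.17 ± 2.48 (list camera adjusted p = 0.154), while adjusted over the list alone 3 rose and 2 fell.

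The lists of spermatogonia and of S phase genes were higher in KO leptotene libraries at the preset correlation but not with an estimated one (adjusted p = 0.54 to 0.646), with few members called. Of 16 differentiating spermatogonia genes 2 rose, and adjusted over the list alone 9 rose and 1 fell. The differentiating spermatogonia list had a median log2 fold change of 1.16 (camera adjusted p = 2.97e-07, and adjusted p = 0.54 with an estimated correlation). The 2 called members were Crabp1, a retinoic acid-binding protein (14 ± 3.08 in WT and 52.3 ± 18.5 in KO), and Uchl1, a deubiquitinase abundant in spermatogonia (65.9 ± 2.41 in WT and 179 ± 46 in KO). None of the 19 undifferentiated spermatogonia genes passed singly, over all genes or adjusted over the list alone. As a list they had a median log2 fold change of 0.99 (camera adjusted p = 2.69e-04, and adjusted p = 0.54 with an estimated correlation). Zbtb16, the most abundant of them, measured 23.4 ± 8.67 in WT and 42.2 ± 3.85 in KO. Of 18 S phase genes 2 rose, or 5 adjusted over the list alone. The S phase list had a median log2 fold change of 0.48 (camera adjusted p = 3.10e-04, and adjusted p = 0.646 with an estimated correlation). The called genes were the replication licensing factors Cdt1 (11 ± 2.41 in WT and 46 ± 4.16 in KO) and Mcm2 (28.3 ± 1.0 in WT and 73.4 ± 5.95 in KO). Replication-dependent histone genes were among the largest rises, with Hist1h3h at 74.8 ± 1.25 in WT and 313 ± 52.7 in KO and Hist1h3i at 28.7 ± 4.19 in WT and 117 ± 13.6 in KO. Hist1h3b was at 43 ± 3.30 in WT and 182 ± 59.8 in KO and Hist1h3g at 10.7 ± 4.0 in WT and 46.3 ± 11 in KO. Values of single histone genes are uncertain, since near-identical copies share reads. Atpaf1, an assembly factor of the mitochondrial ATP synthase, rose from 2.20 ± 0.293 to 16.2 ± 7.65. Stox1 was listed at 0 in both WT libraries and at 11.8 and 10.3 in KO, Slc25a47 at 0 and at 16.8 and 8.54, and the mitochondrial tRNA gene mt-Ta at 0 and at 30.9 and 35.1.

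The lists of leptotene and zygotene functions did not move as a whole at leptotene. The median log2 fold change was 0.07 (camera adjusted p = 0.329) for meiotic entry, -0.07 (camera adjusted p = 0.949) for double-strand break formation and 0.02 (camera adjusted p = 0.272) for recombination. It was -0.13 (camera adjusted p = 0.391) for the synaptonemal complex and axis, -0.13 (camera adjusted p = 0.803) for telomere attachment and -0.06 (camera adjusted p = 0.885) for sex chromosome silencing factors. Of 36 recombination genes 1 was called, Rnf212, a factor that marks crossover sites, at 0.604 and 2.35 in the WT libraries and 12.5 and 16.9 in KO (adjusted p = 0.0441), and adjusted over the list alone 2 rose and 1 fell. The most abundant members measured 286 ± 145 in WT and 244 ± 104 in KO for Tex101 and 129 ± 14.5 in WT and 133 ± 1.53 in KO for Ewsr1. The meiotic cohesin Stag3 measured 207 ± 88.8 in WT and 188 ± 61.1 in KO. Dync1h1 measured 239 ± 62.8 in WT and 232 ± 68.4 in KO. The histone variant H2afx measured 618 ± 186 in WT and 1041 ± 142 in KO. For telomere attachment, sex chromosome silencing factors and Sertoli cell markers the median, the mean and the direction of the test did not share a sign. The LSD1-CoREST, NuRD and SIN3 repressors had a median of 0.14 (camera adjusted p = 0.26), with Rbbp7 at 124 ± 57.1 in WT and 53.2 ± 2.39 in KO.

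Of the lists of somatic testis cells, those of macrophage and of peritubular and stromal markers passed at the preset correlation, and neither did with an estimated one. Of 15 macrophage markers 1 fell, Aif1, from 87.5 ± 13.3 to 13.7 ± 2.27, or 6 adjusted over the list alone. The macrophage markers list had a median log2 fold change of -2.59 (camera adjusted p = 3.08e-05, and adjusted p = 0.646 with an estimated correlation). Of 14 peritubular and stromal markers 1 was called lower, or 6 adjusted over the list alone. The peritubular myoid and stromal markers list had a median log2 fold change of -1.27 (camera adjusted p = 1.39e-05, and adjusted p = 0.646 with an estimated correlation). That gene, Tagln, was at 9.29 and 11 in WT and listed at 0 in both KO libraries, and at 25.5 and 16 in KO zygotene. Ctgf fell from 86.5 ± 67.3 to 3.52 ± 1.95, and Mgp, an extracellular matrix protein, from 58.8 ± 25.7 to 2.56 ± 2.13. Ly6a fell from 73.2 ± 51.8 to 0.661 ± 0.683 and Fgl2 from 57.6 ± 29.7 to 1.64 ± 0.752. Adamts12 was at 15.9 and 15.7 in WT and listed at 0 in both KO libraries, and so was the lymphocyte marker Cd3d (WT 7.04 and 7.95; 1 of 10 markers called, camera adjusted p = 0.329). Dissociation and stress genes fell as a list with 0 of 19 called. That list had a median log2 fold change of -1.10 (camera adjusted p = 0.00931, and adjusted p = 0.758 with an estimated correlation). It did not pass without WT leptotene replicate 2 (median -0.27, adjusted p = 0.883) or without KO leptotene replicate 1 (median -1.19, adjusted p = 0.08). Jund measured 157 ± 108 in WT and 225 ± 3.71 in KO. Sertoli (median -0.12, camera adjusted p = 0.944), Leydig (median -0.10, camera adjusted p = 0.949), endothelial (median -0.18, camera adjusted p = 0.773) and erythroid markers (median -2.28, camera adjusted p = 0.314) did not pass. Of their most abundant members, Clu measured 107 ± 35.7 in WT and 122 ± 14.2 in KO. Insl3 measured 68.2 ± 62.7 in WT and 86 ± 37.5 in KO. Vwf measured 16.3 ± 4.38 in WT and 17.4 ± 1.88 in KO. The erythroid Hba-a1 separated the libraries of each group, at 41 and 855 in WT and 275 and 2.63 in KO.

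A further 3 lists rose as a whole relative to the other genes, with no called member. Cytosolic ribosomal proteins had a median log2 fold change of 0.28 (camera adjusted p = 5.81e-06, and adjusted p = 0.653 with an estimated correlation). Rps14 measured 265 ± 33.8 in WT and 349.6 ± 126 in KO. For p53 targets and apoptosis there was a median log2 fold change of 0.35 (camera adjusted p = 0.00804, and adjusted p = 0.54 with an estimated correlation). Mdm2 measured 45.6 ± 5.51 in WT and 50 ± 8.75 in KO. The BEN domain family had a median log2 fold change of 0.55 (camera adjusted p = 0.026, and adjusted p = 0.54 with an estimated correlation). Banp measured 22 ± 2.30 in WT and 26.9 ± 9.19 in KO. With the median in brackets, list calls were lost as follows. Without WT leptotene replicate 1 calls were lost for BEN domain family (0.46, adjusted p = 0.0792) and p53 targets and apoptosis (0.33, adjusted p = 0.0652). Without KO leptotene replicate 1 calls were lost for BEN domain family (0.50, adjusted p = 0.0868) and cytosolic ribosomal proteins (0.11, adjusted p = 0.226). Without KO leptotene replicate 2 calls were lost for p53 targets and apoptosis (0.26, adjusted p = 0.0548). X-linked genes did not shift as a list (median -0.04, camera adjusted p = 0.885). All 23 called among 915 fell, as did 274 of the 299 genes called on all chromosomes. Examples are the noncoding 1700003E24Rik (21.7 and 27.3 in WT, 0.24 and 0.15 in KO) and Gm614 (16 and 23.5 in WT, listed at 0 in KO). Adjusted over the list alone 1 X-linked gene rose and 31 fell. Of 42 Y-linked genes 1 was called lower, the multicopy Gm20815, at 4.76 and 5.99 in WT leptotene and listed at 0 in the 6 other libraries (median -0.48, camera adjusted p = 0.234). Hox genes (median -0.33, camera adjusted p = 0.712) and mitochondrially encoded genes (median 0.18, camera adjusted p = 0.20) did not pass. Hoxd8 measured 6.37 ± 0.295 in WT and 2.36 ± 0.799 in KO. In the latter list mt-Rnr1, a mitochondrial ribosomal RNA, fell from 79.2 ± 4.79 to 21.7 ± 4.75 (adjusted p = 0.0396). The leptotene count rests on the whole set of libraries: 0 genes passed without WT leptotene replicate 1, 1 without WT leptotene replicate 2, 0 without KO leptotene replicate 1, 1 without KO leptotene replicate 2, 0 without WT zygotene replicate 1 and 0 without WT zygotene replicate 2, though all 299 genes kept their direction each time. Leaving out a zygotene library cannot alter the leptotene fold changes. The 299 genes were also called on these same libraries, so their kept direction is weak support. limma-voom on estimated reads called 0 genes, with 5165 at an unadjusted p under 0.05 against 4102 with limma on TPM.

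The comparison of KO with WT zygotene cells asks the same question at the stage of synapsis. The round spermatid list was again lower in KO at the preset correlation but not with an estimated one (adjusted p = 0.408), and replication-dependent histone genes were among the largest rises. 201 genes changed, 36 higher and 165 lower (limma, adjusted p under 0.05), all by at least 2-fold, and 20 of them were listed at 0 in both libraries of WT or of KO. Tnp1 fell from 635 ± 36.5 to 40.1 ± 25.6 (log2 fold change -4.10 ± 0.46, adjusted p = 0.0208), and Fabp9, a fatty acid-binding protein of germ cells, from 213 ± 30.4 to 13.3 ± 8.25 (chromosome 3, 10193621 to 10197283, log2 fold change -4.02 ± 0.49). Hist1h2bg rose from 21.9 ± 1.43 to 204 ± 55 (chromosome 13, 23571396 to 23572013, log2 fold change 3.13 ± 0.28, adjusted p = 0.0131).

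Of 30 round spermatid genes 3 fell, or 25 adjusted over the list alone. The list had a median log2 fold change of -1.78 (camera adjusted p = 7.83e-17, and adjusted p = 0.408 with an estimated correlation). Akap4 measured 173 ± 45.5 in WT and 13.9 ± 9.37 in KO. Of 30 pachytene genes 8 fell, and adjusted over the list alone 18 fell and 1 rose. The pachytene list had a median log2 fold change of -1.19 (camera adjusted p = 1.54e-10, and adjusted p = 0.408 with an estimated correlation). Pgk2 measured 93.4 ± 14.2 in WT and 9.20 ± 4.18 in KO. The sperm surface protein Adam3 measured 79.7 ± 17.8 in WT and 8.43 ± 5.08 in KO. Cabs1, a calcium-binding protein of spermatids, fell from 63.9 ± 12.6 to 2.88 ± 0.712, Cypt12 from 48.8 ± 4.39 to 1.80 ± 1.53, and H2al2a, a histone variant of condensing spermatids with near-identical copies, from 66.8 ± 6.67 to 4.31 ± 3.53. Tdrd6 was the 1 called piRNA gene of 27 (46.2 ± 12.3 in WT and 8.71 ± 4.60 in KO; list camera adjusted p = 0.0796). Il4i1, an amino acid oxidase, fell from 17.8 ± 2.49 to 0.0864 ± 0.0488, and the mucin Muc16 was at 24.8 and 12.9 in WT and listed at 0 in KO. Hist1h2bq, Slc25a47 and mt-Ta were at 55 and 50.2, 21.5 and 9.71 and 36.4 and 28.5 in WT and listed at 0 in both KO libraries.

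On the rising side, Hist1h3b measured 19.5 ± 7.20 in WT and 133 ± 39.7 in KO, and Hist1h3c 32.4 ± 16.3 in WT and 199 ± 50.2 in KO. Hist1h3d was at 19.9 ± 5.26 in WT and 122 ± 21.9 in KO and Hist1h3e at 11.1 ± 1.21 in WT and 91.4 ± 25.8 in KO. Values were 9.65 ± 3.12 in WT and 64.4 ± 11 in KO for Hist2h3c2 and 2.46 ± 3.27 in WT and 47.6 ± 10.6 in KO for Hist2h3c1, with the same doubt about near-identical copies. Rasgrp1, an activator of Ras, was at 0 and 0.31 in WT and 13.8 and 8.67 in KO. Lgals2 and Ripor3 were listed at 0 in WT and at 7.27 and 6.69 and 4.40 and 7.38 in KO. Of 16 differentiating spermatogonia genes 1 rose, Crabp1 (13.2 ± 2.37 in WT and 57.9 ± 13 in KO), and adjusted over the list alone 13 rose and 1 fell. The differentiating spermatogonia list had a median log2 fold change of 1.21 (camera adjusted p = 2.32e-09, and adjusted p = 0.408 with an estimated correlation). Of 19 undifferentiated spermatogonia genes 0 rose over all genes and 2 adjusted over the list alone. The undifferentiated spermatogonia list had a median log2 fold change of 0.80 (camera adjusted p = 6.49e-04, and adjusted p = 0.408 with an estimated correlation). Of 18 S phase genes 0 rose over all genes and 7 adjusted over the list alone. The S phase list had a median log2 fold change of 0.68 (camera adjusted p = 2.57e-08, and adjusted p = 0.408 with an estimated correlation). Values were 9.29 ± 1.95 in WT and 34.1 ± 14.2 in KO for Cdt1 and 25.3 ± 1.72 in WT and 66.6 ± 16.8 in KO for Mcm2. Among X-linked genes 2 rose, Sox3, a transcription factor of spermatogonia (9.34 ± 0.017 in WT and 34.3 ± 7.04 in KO), and Hdac6, a tubulin deacetylase (40.4 ± 6.73 in WT and 96.4 ± 8.55 in KO). Another 16 X-linked genes fell, among them 1700003E24Rik and 1700010D01Rik, at 15.2 and 21.4 in WT and listed at 0 in KO, and adjusted over the list alone 9 rose and 35 fell (median -0.00, camera adjusted p = 0.864).

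At zygotene 4 further lists rose relative to the other genes, with no called member. Recombination genes had a median log2 fold change of 0.18 (camera adjusted p = 0.0362, and adjusted p = 0.556 with an estimated correlation). The LSD1-CoREST, NuRD and SIN3 repressors had a median log2 fold change of 0.17 (camera adjusted p = 0.0348, and adjusted p = 0.408 with an estimated correlation). The p53 targets and apoptosis genes had a median log2 fold change of 0.30 (camera adjusted p = 0.0165, and adjusted p = 0.408 with an estimated correlation). Cytosolic ribosomal proteins had a median log2 fold change of 0.27 (camera adjusted p = 9.10e-06, and adjusted p = 0.628 with an estimated correlation). Meiotic entry (median 0.12, camera adjusted p = 0.221), double-strand break formation (median 0.16, camera adjusted p = 0.298), the synaptonemal complex and axis (median -0.02, camera adjusted p = 0.956), telomere attachment (median 0.03, camera adjusted p = 0.586), sex chromosome silencing factors (median 0.26, camera adjusted p = 0.0655) and the BEN domain family (median 0.46, camera adjusted p = 0.10) did not pass. Macrophage markers fell in the same libraries, with 1 of 15 called, Aif1 (79.1 ± 12.1 in WT and 16.8 ± 9.26 in KO). They had a median log2 fold change of -1.72 (camera adjusted p = 4.94e-05, and adjusted p = 0.556 with an estimated correlation). Peritubular and stromal, lymphocyte, and dissociation and stress genes fell as lists with no called member. Peritubular and stromal markers had a median log2 fold change of -0.82 (camera adjusted p = 0.00611, and adjusted p = 0.637 with an estimated correlation). Lymphocyte markers had a median log2 fold change of -0.93 (camera adjusted p = 0.0362, and adjusted p = 0.408 with an estimated correlation). Dissociation and stress genes had a median log2 fold change of -0.99 (camera adjusted p = 0.0297, and adjusted p = 0.72 with an estimated correlation). Lists lost their call as follows, with the median in brackets. Without WT zygotene replicate 1 calls were lost for lymphocyte markers (-0.95, adjusted p = 0.0611). Without WT zygotene replicate 2 calls were lost for recombination and break repair (0.17, adjusted p = 0.282), LSD1-CoREST, NuRD and SIN3 repressors (0.12, adjusted p = 0.121), dissociation and stress response (-0.31, adjusted p = 0.696), peritubular myoid and stromal markers (-0.52, adjusted p = 0.251), macrophage markers (-0.68, adjusted p = 0.0572) and lymphocyte markers (-1.05, adjusted p = 0.0526). Without KO zygotene replicate 1 calls were lost for p53 targets and apoptosis (0.39, adjusted p = 0.103) and lymphocyte markers (-0.64, adjusted p = 0.327). Without KO zygotene replicate 2 calls were lost for recombination and break repair (0.20, adjusted p = 0.148), LSD1-CoREST, NuRD and SIN3 repressors (0.24, adjusted p = 0.168), dissociation and stress response (-0.64, adjusted p = 0.22) and peritubular myoid and stromal markers (-0.27, adjusted p = 0.267). Sertoli (median -0.56, camera adjusted p = 0.0554), Leydig (median 0.15, camera adjusted p = 0.879), endothelial (median -0.09, camera adjusted p = 0.893), erythroid (median -2.49, camera adjusted p = 0.562), Hox (median -0.15, camera adjusted p = 0.879), mitochondrially encoded (median 0.09, camera adjusted p = 0.614) and Y-linked genes (median -0.38, camera adjusted p = 0.586) did not pass. The median, the mean and the direction of the test did not share a sign for synaptonemal complex and axis, telomere attachment, Leydig cell markers, endothelial markers, Hox genes, mitochondrially encoded genes and X-linked genes. The zygotene count fell to 1 without WT zygotene replicate 1, 1 without WT zygotene replicate 2, 1 without KO zygotene replicate 2, 2 without WT leptotene replicate 1, 2 without WT leptotene replicate 2, 20 without KO zygotene replicate 1, 60 without KO leptotene replicate 1 and 72 without KO leptotene replicate 2, though all 201 genes kept their direction. The number of lists called went from 13 to 7 without WT zygotene replicate 2. Leaving out a leptotene library cannot alter the zygotene fold changes. The 201 genes were also called on these same libraries, so their kept direction is weak support. With no filter on low values 1 gene passed, and limma-voom on estimated reads called 0, with 5324 genes at an unadjusted p under 0.05 against 3804 with limma on TPM.

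**Figure D2:**
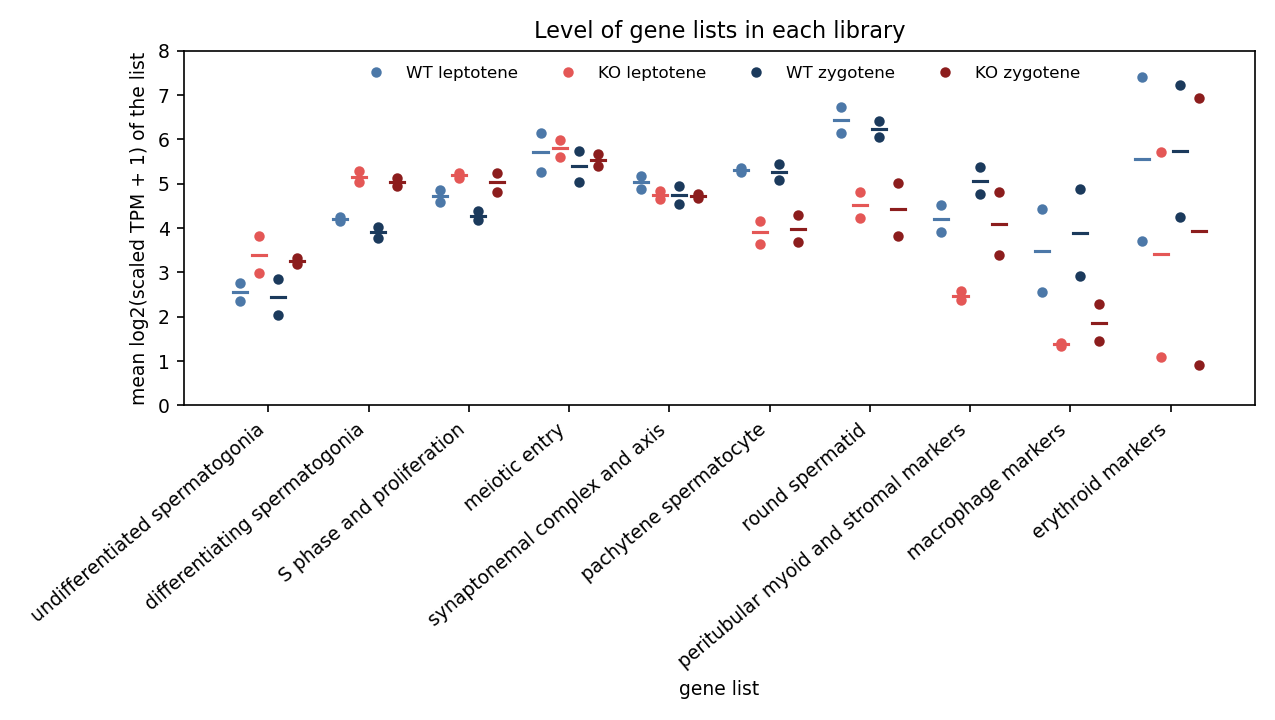
Mean log2(scaled TPM + 1) over the genes of 10 lists (y axis) in each library; points are the 2 libraries of a group, bars their mean, and colours the 4 groups. Round spermatid and pachytene lists lie lower in all 4 KO libraries than in all 4 WT libraries and the differentiating spermatogonia list higher, while erythroid markers part the 2 libraries of every group.

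The calls of the 2 stages, which share no library but share 1 variance estimate per gene, were set against each other to ask whether the same genes moved. The tests below take the stages as independent, which was not shown, and Hba-a1 differed by replicate number alike at both stages. They also take genes as independent, although list members moved together (estimated correlation 0.735 for the round spermatid list). A shared variance estimate can also favour calls of the same gene at both stages, so the numbers for independent lists are too low a standard. Of the 25 and 36 genes higher in KO at leptotene and zygotene, 10 were shared, where independent lists would share 0.039 (one-sided Fisher's exact test, p = 6.98e-23). Of the 274 and 165 lower genes 128 were shared, where independent lists would share 1.96 (one-sided Fisher's exact test, p = 1.25e-225). Tnp1, Cabs1, Txndc2, Hmgb4, Pgk2 and Akap4 were lower at both stages, and Crabp1, Cdkn2a, Hist1h3b and Hist1h3i higher at both. Across genes, which are not independent replicates, the log2 fold changes correlated with r = 0.54. Called at both stages in opposite directions were 3 genes, Stox1, Slc25a47 and mt-Ta, each listed at 0 in both libraries of at least 1 group. No gene was shared in either direction without WT leptotene replicate 1 or 2, KO leptotene replicate 1, WT zygotene replicate 1 or 2, or KO zygotene replicate 2. 1 lower gene was shared without KO leptotene replicate 2, and 16 lower and 1 higher without KO zygotene replicate 1.

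**Figure D3:**
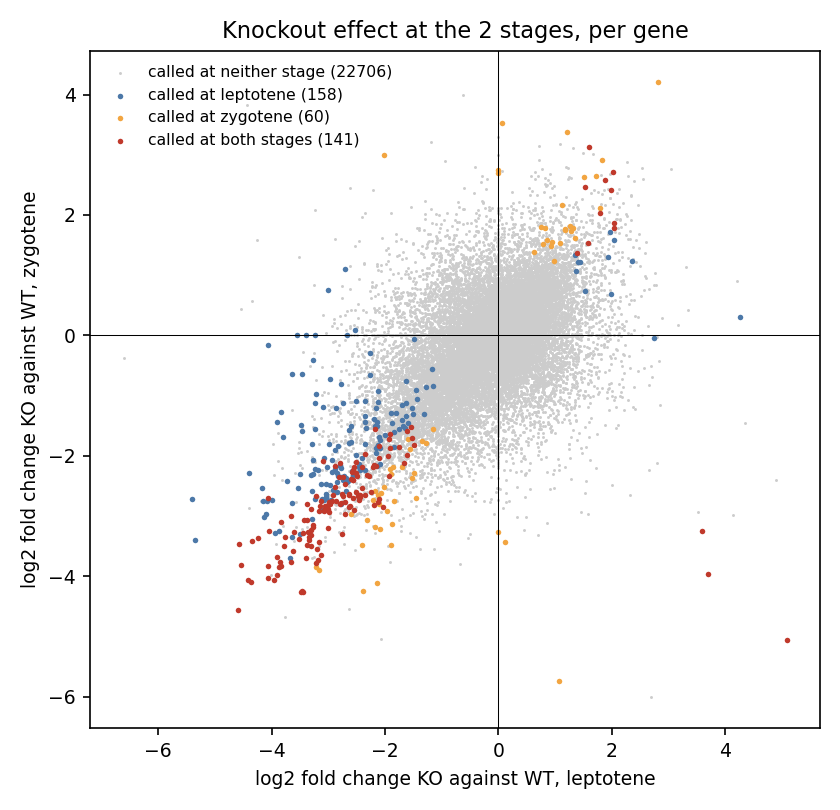
Log2 fold change of KO against WT at leptotene (x axis) and zygotene (y axis) for each of the 23065 genes tested; colours give the stage at which a gene was called (limma, adjusted p under 0.05). The 128 genes lower at both stages lie at the lower left and the 10 higher at both at the upper right.

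Whether the knockout effect depends on the stage was tested by the interaction. The effect differed for 2 genes, the histone gene Hist1h2bq (adjusted p = 2.66e-04, limma) and the mitochondrial tRNA gene mt-Ta (adjusted p = 0.00114), and both are listed at 0 in at least 1 group. Hist1h2bq was at 124 and 119 in WT leptotene, 272 and 239.9 in KO leptotene and 55 and 50.2 in WT zygotene, and listed at 0 in KO zygotene, and near-identical copies make its value uncertain. 840 genes had an unadjusted p under 0.05, where chance gives 1153, and 1026 with the covariate for the kind of library. None of the 28 lists passed (smallest camera adjusted p = 0.128, for peritubular and stromal and for Sertoli markers), and the median, the mean and the direction of the test did not share a sign for telomere attachment, Leydig cell markers, erythroid markers and cytosolic ribosomal proteins. Of genes, 1 passed without WT zygotene replicate 1 and 1 without WT zygotene replicate 2, while lists numbered 3 without WT leptotene replicate 1, 7 without WT leptotene replicate 2, 2 without KO leptotene replicate 1, 2 without KO leptotene replicate 2, 1 without WT zygotene replicate 1, 1 without WT zygotene replicate 2, 2 without KO zygotene replicate 1 and 5 without KO zygotene replicate 2. On simulated data, the interaction recovered 0%, 6%, 32% and 28% of genes changed 2-, 4-, 8- and 16-fold, with 50 genes at each fold. In that setting, with independent noise, most large stage-dependent effects were missed.

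Zygotene was compared with leptotene within each genotype to ask which genes follow the stage. In WT, 2 genes were called, both higher in zygotene: Stox1, listed at 0 in both leptotene libraries and at 52.3 and 34.8 in zygotene (adjusted p = 0.0456), and mt-Ta, at 0 and at 36.4 and 28.5 (adjusted p = 0.036). Neither gene passed with the replicate number as a block or with the covariate for the kind of library. In simulated data 0%, 32%, 46% and 78% of genes changed 2-, 4-, 8- and 16-fold in this comparison were recovered, with 3 false calls. Few calls thus do not show that few genes follow the stage. In WT the lists of S phase, recombination, double-strand break formation, the synaptonemal complex and differentiating spermatogonia fell. The S phase list had a median log2 fold change of -0.50 (camera adjusted p = 1.21e-05, and adjusted p = 0.584 with an estimated correlation). Recombination genes had a median log2 fold change of -0.37 (camera adjusted p = 3.75e-04, and adjusted p = 0.584 with an estimated correlation). Double-strand break genes had a median log2 fold change of -0.34 (camera adjusted p = 0.0339, and adjusted p = 0.584 with an estimated correlation). The synaptonemal complex and axis had a median log2 fold change of -0.31 (camera adjusted p = 0.0339, and adjusted p = 0.584 with an estimated correlation). The differentiating spermatogonia list had a median log2 fold change of -0.34 (camera adjusted p = 0.0401, and adjusted p = 0.584 with an estimated correlation). Peritubular and stromal markers, p53 targets and dissociation and stress genes rose in the same libraries. Peritubular and stromal markers had a median log2 fold change of 0.86 (camera adjusted p = 1.21e-05, and adjusted p = 0.584 with an estimated correlation). The p53 list had a median log2 fold change of 0.27 (camera adjusted p = 0.0339, and adjusted p = 0.584 with an estimated correlation). Stress genes had a median log2 fold change of 0.61 (camera adjusted p = 0.0339, and adjusted p = 0.761 with an estimated correlation). No member of these lists was called over all genes, and adjusted over the list alone 1 recombination gene rose and 1 fell. The stress list had a median of -0.36 without WT leptotene replicate 1 and -0.11 without WT zygotene replicate 2. Lists called went from 8 to 4 without WT leptotene replicate 1, 14 without WT leptotene replicate 2 and 2 without WT zygotene replicate 2, and mitochondrially encoded genes had a median of 0.43 without WT leptotene replicate 1. In WT, list calls depend on single libraries, with the median in brackets. Without WT leptotene replicate 1 calls were lost for differentiating spermatogonia (-0.34, adjusted p = 0.216), double-strand break formation (-0.10, adjusted p = 0.987), recombination and break repair (-0.19, adjusted p = 0.391), synaptonemal complex and axis (-0.05, adjusted p = 0.845) and p53 targets and apoptosis (0.12, adjusted p = 0.337). Without WT leptotene replicate 2 calls were lost for differentiating spermatogonia (-0.18, adjusted p = 0.0763). Without WT zygotene replicate 1 calls were lost for differentiating spermatogonia (-0.06, adjusted p = 0.329) and p53 targets and apoptosis (0.35, adjusted p = 0.0785). Without WT zygotene replicate 2 calls were lost for double-strand break formation (-0.18, adjusted p = 0.342), recombination and break repair (-0.28, adjusted p = 0.126), synaptonemal complex and axis (-0.13, adjusted p = 0.725), p53 targets and apoptosis (0.22, adjusted p = 0.126) and peritubular myoid and stromal markers (0.61, adjusted p = 0.0545). Median, mean and test differed in sign for telomere attachment, BEN domain family, erythroid markers and X-linked genes. Meiotic entry (median -0.34, camera adjusted p = 0.0553), pachytene (median -0.02, camera adjusted p = 0.91) and round spermatid genes (median -0.21, camera adjusted p = 0.106) did not pass.

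In KO, 4 genes were called between the stages. Of these, 1 also passed with the replicate number as a block and 3 with the covariate for the kind of library. In simulated data 0%, 18%, 58% and 78% of genes changed 2-, 4-, 8- and 16-fold in this comparison were recovered, with 5 false calls. Tagln, an actin-binding protein of smooth muscle, and Ecm2, an extracellular matrix protein, were listed at 0 in both leptotene libraries and were at 25.5 and 16 and 12.5 and 19 in zygotene (adjusted p = 0.0452 and 0.0452). Hist1h2bq and mt-Ta were at 272 and 239.9 and at 30.9 and 35.1 in leptotene and listed at 0 in zygotene. Peritubular and stromal markers rose, with 1 of 14 called and 7 adjusted over the list alone. They had a median log2 fold change of 1.20 (camera adjusted p = 7.73e-10, and adjusted p = 0.854 with an estimated correlation). Stress, endothelial and Hox genes also rose as lists. Dissociation and stress genes had a median log2 fold change of 0.73 (camera adjusted p = 0.00624, and adjusted p = 0.854 with an estimated correlation). Endothelial markers had a median log2 fold change of 0.55 (camera adjusted p = 0.0208, and adjusted p = 0.854 with an estimated correlation). Hox genes had a median log2 fold change of 0.59 (camera adjusted p = 0.00624, and adjusted p = 0.854 with an estimated correlation). Mitochondrially encoded, Sertoli and recombination genes fell as lists. Mitochondrially encoded genes had a median log2 fold change of -0.41 (camera adjusted p = 4.30e-05, and adjusted p = 0.854 with an estimated correlation). Sertoli markers had a median log2 fold change of -0.42 (camera adjusted p = 0.00792, and adjusted p = 0.854 with an estimated correlation). Recombination genes had a median log2 fold change of -0.24 (camera adjusted p = 0.0208, and adjusted p = 0.854 with an estimated correlation). The S phase list (median -0.19, camera adjusted p = 0.0744), meiotic entry (median -0.23, camera adjusted p = 0.142), pachytene (median 0.00, camera adjusted p = 0.614) and round spermatid genes (median -0.05, camera adjusted p = 0.47) did not pass. Lists called went from 7 to 2 without KO zygotene replicate 1 and 14 without KO zygotene replicate 2, the latter with a round spermatid median of 0.53. List calls in KO depend on single libraries too. Without KO leptotene replicate 1 calls were lost for dissociation and stress response (0.86, adjusted p = 0.103), Sertoli cell markers (-0.27, adjusted p = 0.262), endothelial markers (0.48, adjusted p = 0.259) and Hox genes (0.62, adjusted p = 0.0512). Without KO leptotene replicate 2 calls were lost for recombination and break repair (-0.12, adjusted p = 0.364) and mitochondrially encoded genes (-0.24, adjusted p = 0.0938). Without KO zygotene replicate 1 calls were lost for recombination and break repair (-0.06, adjusted p = 0.275), dissociation and stress response (0.42, adjusted p = 0.28), Sertoli cell markers (-0.44, adjusted p = 0.255), endothelial markers (0.17, adjusted p = 0.736), Hox genes (0.00, adjusted p = 0.374) and mitochondrially encoded genes (-0.15, adjusted p = 0.255). The median of Y-linked genes was 0 and their mean negative. Without any single library 0 genes passed in WT, except 1 without WT leptotene replicate 2, and 1 passed in KO, except 2 without WT leptotene replicate 1 or 2. At an unadjusted p under 0.05 there were 911 genes in WT and 1202 in KO, where chance gives 1153. With the covariate for the kind of library there were 1472 and 1572, so the number depends on how the kind of library is treated. limma-voom called 0 in both, with 1140 and 1146 at an unadjusted p under 0.05.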

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

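The interaction, the list tests and the test of the scaling were set before their results were seen, while the comparison within kinds of library, the counts of members, the comparison with meiotic lists and the exon tests were chosen after. The effect of the knockout differed between the stages for 2 genes by the interaction in limma, and no cause was tested for either. For Hist1h2bq the log2 difference was -6.81 ± 0.30 (adjusted p = 2.66e-04), with KO zygotene listed at 0. For mt-Ta it was -10.14 ± 0.59 (adjusted p = 0.00114), with WT leptotene and KO zygotene listed at 0. Both sizes depend on the pseudocount, and neither is a fold.

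The pachytene and round spermatid lists were lower in KO at leptotene and zygotene at the preset correlation but not with an estimated one (adjusted p = 0.408 to 0.54), with 8 and 8 of 30 pachytene and 4 and 3 of 30 spermatid genes called. For the round spermatid list the scaling factors, from 0.929 to 1.14, were too small to be the whole cause. With TPM as deposited the median log2 fold changes were -2.03 and -1.92, which such factors could hardly alter. The scaling to a total that TPM itself holds was not removed. Each group held 1 library of each kind, so a shift by kind common to all groups would cancel between KO and WT. Between KO and WT libraries of a kind the median log2 differences ran from -2.00 to -1.48, so neither kind alone carried the fall. RNA of pachytene spermatocytes and spermatids in the WT sorts and a change of these genes within leptotene and zygotene cells cannot be told apart, since either would lower the members together. Of 56 members with a mean WT TPM of at least 10, 47 (83.9%) were lower in every KO than in every WT library at both stages. Chance gives 16.7% per gene at 1 stage, and the stages are not known to be independent. The filter on the WT level favours members that are lower in KO, which that chance share does not allow for. Tnp1 was at 809 ± 289 in WT leptotene and 635 ± 36.5 in WT zygotene, and 18 genes stand in more than 1 list. The macrophage list also fell (median log2 fold change -2.59 and -1.72, adjusted p = 0.646 and 0.556 with an estimated correlation, 1 and 1 of 15 called), and no test separated an effect of the loss of Bend2 from other cells in the sorts.

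The spermatogonial and S phase lists were higher in KO at leptotene and zygotene at the preset correlation but not with an estimated one (adjusted p = 0.408 to 0.646), with 2 and 1 of 16 differentiating, 0 and 0 of 19 undifferentiated and 2 and 0 of 18 S phase genes called. Dilution by RNA of later cells in the WT sorts stays open, since the meiotic lists used for comparison hold genes that pachytene cells express too: the median log2 fold change of the differentiating spermatogonia list exceeded theirs by 1.16 at leptotene (95% bootstrap interval over genes 0.55 to 1.51) and 1.09 at zygotene (0.77 to 1.69). The intervals resample genes measured in the same libraries, so they take genes as independent and hold no spread between libraries. More spermatogonia or preleptotene cells in the KO sorts and a change of these genes within the sorted cells cannot be told apart, since either would raise the members together. At both stages 32 of 39 members with a mean TPM of at least 10 (82%) had a positive log2 fold change in KO. The share over all genes of that level was not computed, so this count has no background to set it against. Crabp1 was at 52.3 ± 18.5 and Uchl1 at 179 ± 46 in KO leptotene.

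Exons 12 and 13 of Gm15262 had little coverage in KO beside exons 11 and 14. Their mean coverage was 17.1 and 4.84 in KO leptotene and 9.16 and 0 in KO zygotene. It was 72.4 and 16.4 in WT leptotene and 40.3 and 50.4 in WT zygotene. Only KO zygotene replicate 2 was thus at 0, and KO leptotene replicate 1 lay above WT leptotene replicate 2. Lower coverage of the whole gene is argued against, since exons 11 and 14 in KO had 152% of their WT coverage and exons 12 and 13 had 17.3%. A candidate explanation is that these exons are missing from much of the RNA of KO libraries, with the ratio at most 0.182 in KO and at least 0.455 in WT (two-sided exact permutation test, p = 0.0286, the smallest possible). Since the exons were chosen on these libraries and the test takes the libraries of 2 stages as independent, the p is not independent evidence.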

How the results depend on the processing

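The loci of the files, covered bases and the covariate for the kind of library were tried only after the data were seen. In the main analysis 299 KO leptotene, 201 KO zygotene, 2 interaction, 2 WT stage and 4 KO stage genes passed, with 11, 13, 0, 8 and 7 lists, and 10 higher and 128 lower genes shared between stages. The number of calls depends strongly on the processing, and the cause was not tested unless named. A pseudocount of 0.1 gave 84 KO zygotene genes, 0 WT stage genes, 4 shared higher genes, 56 shared lower genes. A pseudocount of 5 gave 2 KO stage genes. No filter on low values gave 82 KO leptotene genes, 1 KO zygotene gene, 0 WT stage genes, 4 WT stage lists, 1 KO stage gene, 0 shared higher genes, 0 shared lower genes. A TPM of at least 5 gave 529 KO leptotene genes, 359 KO zygotene genes, 27 shared higher genes, 246 shared lower genes. TPM as deposited gave 318 KO zygotene genes, 226 shared lower genes. Quantile normalization gave 335 KO zygotene genes, 1 WT stage gene, 24 shared higher genes. FPKM gave 502 KO leptotene genes, 381 KO zygotene genes, 2 KO stage genes, 25 shared higher genes, 263 shared lower genes. limma-voom on estimated reads gave 0 KO leptotene genes, 0 KO zygotene genes, 0 interaction genes, 2 interaction lists, 0 WT stage genes, 13 WT stage lists, 0 KO stage genes, 0 shared higher genes, 0 shared lower genes. Reference transcripts only gave 190 KO leptotene genes, 2 interaction lists, 0 WT stage genes, 2 KO stage genes. Only the 4 libraries of a comparison, with fewer degrees of freedom, gave 0 KO leptotene genes, 0 KO zygotene genes, 0 WT stage genes, 3 WT stage lists, 0 KO stage genes, 0 shared higher genes, 0 shared lower genes. Without the intensity trend there were 46 KO zygotene genes, 1 WT stage gene, 2 KO stage genes, 1 shared higher gene, 31 shared lower genes. An estimated correlation in camera gave 0 KO leptotene lists, 0 KO zygotene lists, 0 WT stage lists, 0 KO stage lists. The loci of the files gave 565 KO leptotene genes, 501 KO zygotene genes, 5 interaction genes, 2 interaction lists, 5 WT stage genes, 12 KO stage genes, 23 shared higher genes, 273 shared lower genes. Covered bases gave 880 KO leptotene genes, 608 KO zygotene genes, 2 interaction lists, 1 WT stage gene, 2 KO stage genes, 74 shared higher genes, 355 shared lower genes. The covariate for the kind of library gave 884 KO leptotene genes, 806 KO zygotene genes, 0 WT stage genes, 58 shared higher genes, 492 shared lower genes. With 2 numbers per group, a pairing of the libraries by number cannot be established, and the stage and interaction tests do not pair them. Within a genotype the kind of library and Hba-a1 followed the number at both stages, with replicate 1 of WT like replicate 2 of KO. The replicate block instead sets equal numbers of WT and KO together, so it does not test that grouping. Deviations of same-numbered libraries correlated with r = -0.084 between WT and KO at leptotene and r = -0.0945 at zygotene, and with r = 0.19 between the stages in WT and r = 0.106 in KO. The replicate block gave 71 KO leptotene genes, 20 KO zygotene genes, 0 WT stage genes, 1 KO stage gene, 0 shared higher genes, 13 shared lower genes, and changed no other count by over 1.5 times. Leaving out each library in turn, which assumes that the lone library left varies like the other groups, gave 0 to 259 KO leptotene genes, 1 to 72 KO zygotene genes, 1 to 3 interaction genes, 0 to 1 WT stage genes, 1 to 2 KO stage genes, 9 to 12 KO leptotene lists, 7 to 15 KO zygotene lists, 1 to 7 interaction lists, 2 to 14 WT stage lists, 2 to 14 KO stage lists, 0 to 1 shared higher genes, 0 to 16 shared lower genes and r across genes from 0.408 to 0.545. The direction of a list test turned for Hox genes in KO zygotene (-1.05, reference transcripts only), dissociation and stress response in WT stage (-0.36, without WT leptotene replicate 1), mitochondrially encoded genes in WT stage (0.43, without WT leptotene replicate 1), dissociation and stress response in the interaction (-0.67, without WT leptotene replicate 2), cytosolic ribosomal proteins in the interaction (0.23, without KO leptotene replicate 1), cytosolic ribosomal proteins in KO stage (-0.15, without KO leptotene replicate 2), dissociation and stress response in WT stage (-0.11, without WT zygotene replicate 2), round spermatid in the interaction (-0.45, without KO zygotene replicate 1), round spermatid in KO stage (0.53, without KO zygotene replicate 2), Hox genes in KO zygotene (-1.09, loci of the files), where a list that passed neither way is not counted. Leaving out each library, list medians ran for cytosolic ribosomal proteins in the interaction from -0.22 to 0.23, cytosolic ribosomal proteins in KO stage from -0.15 to 0.32, dissociation and stress response in the interaction from -0.67 to 1.17, dissociation and stress response in WT stage from -0.36 to 1.56, mitochondrially encoded genes in WT stage from -0.84 to 0.43, round spermatid in the interaction from -0.45 to 0.71, round spermatid in KO stage from -0.63 to 0.53. Over all alternatives, values of named genes stayed on their side of the threshold 832 times, lost the call with the same direction 860 times and turned 0 times, and list values did so 2933, 105 and 10 times, with 129 gaining a call. Apart from Gm15262, the named genes counted here had been called on these same libraries. Some alternatives, such as no intensity trend, cannot alter a fold change, so the lack of turns was largely fixed beforehand. TPM as deposited moved the median log2 fold change of all genes to -0.11 at leptotene and -0.16 at zygotene. No alternative was run for Bend2, which has no gene under that symbol here.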

Other observations

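The list of histone cluster genes was taken by symbol alone, with no check that each is replication-dependent. The list and its tests were chosen after values were seen. Of 70 tested, 7 rose in KO leptotene, or 39 adjusted over the list alone (median log2 fold change 1.08, limma's camera p = 5.79e-25, p = 0.0594 with an estimated correlation). In KO zygotene 15 rose and 1 fell, Hist1h2bq, or 55 and 1 adjusted over the list alone (median 1.52, camera p = 3.91e-35, p = 0.0351 with an estimated correlation). From leptotene to zygotene none was called in WT and 1 fell in KO, or 33 and 1 fell adjusted over the list alone, with medians of -1.05 (p = 0.0253 with an estimated correlation in limma's camera) and -0.54 (p = 0.0907), and the interaction median was 0.42 (p = 0.323). Near-identical copies share reads, so the family is more certain than its single genes.

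The libraries fell into 2 kinds that the groups do not explain. Unannotated single-exon transcripts held 12.5% and 23.8% of TPM in WT leptotene replicates 1 and 2, 22.3% and 14.4% in KO leptotene, 9.90% and 23.7% in WT zygotene, and 24% and 11.9% in KO zygotene. The low shares were those of replicate 1 in WT and replicate 2 in KO at both stages. Hba-a1 also differed by replicate number alike at both stages, at 41 and 855 in WT leptotene, 106 and 925 in WT zygotene, 275 and 2.63 in KO leptotene and 632 and 1.97 in KO zygotene. The noncoding genes Rn7s1, Rn7s2, Rn7sk, Rmrp and Gm26917 together held between 24.1% and 39% of TPM and mitochondrial transcripts between 3.67% and 8.70%.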
